A study of Homo sapiens with 4 samples.

How the data were processed

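RNA sequencing of polyadenylated RNA was analysed from 4 libraries of HaCaT, an immortalised human keratinocyte line. Per the labels, 2 libraries came from cells given phosphate-buffered saline (PBS) and 2 from cells given M5, a mix of 5 cytokines at 10 μg/L each, for 72 h from a plating density of 50%. Groups and replicate numbers were taken from the sample titles. The treatment tag of both M5 libraries names a 25 μM dose of an agent abbreviated DAC instead, while the titles, the protocols and the series description name M5, so the titles were followed. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

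Each deposited file held, per the file headers, a read count and an FPKM value (fragments scaled by gene length and library total) for the same 27356 Ensembl genes. The submitters' processing notes name HISAT2, HTSeq 0.13.5 and the build GRCh38, without roles or order. The version of HISAT2, the annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. The deposited FPKM were made from the deposited counts and each file's own total: dividing count by FPKM gave whole-number gene lengths to within 3.1e-08 bp. All rows named a gene, and 6616 carried only an Ensembl identifier. The library kit named in the protocol does not mark strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart. Positions were taken from GENCODE 29 on GRCh38, which holds 25496 (93.2%) of the identifiers.

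The test planned before the data were examined was limma on log2(FPKM + 1), on the assumption that only FPKM would be given. Because the files also hold counts, the main test became edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) with TMM scaling, two-sided, on genes with a mean FPKM of at least 1 over the 4 libraries, and the planned limma test (limma 3.58.1) was kept as an alternative. The p-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 are called changed. The 34 gene lists were fixed before the data were examined. Those with at least 5 tested members, 27 lists, were compared with the other tested genes by camera at its preset correlation of 0.01, with adjustment over the lists. Standard errors are the log2 fold change divided by the square root of its F statistic. Levels are CPM scaled by TMM, as mean ± SD over 2 libraries.

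A fold against a group with 0 counts is a lower bound, computed against a floor of 3 counts over the 2 libraries of that group together. With 1 to 3 counts in a group the ratio is given with its exact (Clopper-Pearson) 95% interval. These floors and intervals cover counting error only. In a single library, 3 counts correspond to between 0.152 and 0.189 CPM.

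The named genes followed a rule fixed before the data were examined. They are the 8 largest rises and 8 largest falls in log2 fold change among changed genes with a symbol, up to 3 changed members with the largest absolute change of each list that camera called or that had at least 3 changed members, the most abundant gene of each list of other cell types and of the germline list, and the 5 cytokines of M5 as genes. Some genes that the rule selects are not reported here. Genes outside this rule are said to be chosen after their values were seen.

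On counts simulated for the 10809 tested genes of this comparison, with 200 genes changed, the edgeR step recovered 48% of genes changed 1.25-fold, 80% at 1.5-fold, 88% at 2-fold and all 50 at 4-fold. In that simulation 4.8% of its calls were false, and camera gave an unadjusted p under 0.05 to 0 of 200 random lists. Each gene was drawn independently, the random lists held only unchanged genes, and fewer genes were changed than the 55.9% called in the data. The simulation therefore does not show how often camera calls lists whose genes vary together, with estimated correlations of up to 0.66 here. Alternatives planned before the data were examined were pseudocounts of 0.1 and 0.5, quantile normalization, no trend and a robust fit (all in limma), no filter, a mean FPKM of at least 5, TPM and median-of-ratios scaling, a replicate block, each library left out, an adjusted p of 0.01, camera with an estimated correlation, and fry. Chosen after seeing the data were limma on log2(FPKM + 1) as an alternative, DESeq2 1.42.0, library totals without TMM factors, the robust edgeR fit, and the tests without genes discordant between replicates or with a transcript outside the primary assembly.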

Results

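The effect of M5 on the transcriptome of HaCaT keratinocytes was measured after 72 h by RNA sequencing, with 2 PBS and 2 M5 libraries. M5 combines interleukin 1α, interleukin 17, interleukin 22, TNF-α and oncostatin M. The PBS libraries held 15858644 and 16051974 counts and the M5 libraries 18992988 and 19749612. The libraries of a group differed by more than sampling noise, with a median chi-square per gene of 0.976 in PBS and 1.434 in M5 where sampling alone gives 0.455, so neither pair was treated as copies of 1 library. This excess does not tell separate cultures from separate library preparations. Mitochondrially encoded mRNA made up 4.29% and 4.09% of the PBS counts and 3.42% and 3.73% of the M5 counts.

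The largest rises with M5 included the chemokine CXCL5, the alarmin S100A9 and the serpin SERPINB4, and the largest falls the keratins KRT4 and KRT13 and the alkaline phosphatases ALPG and ALPP. CXCL5, a neutrophil-attracting chemokine (ENSG00000163735, chromosome 4, 73995642 to 73998779), had 0 counts in both PBS libraries and 425 ± 40.4 CPM (SD, n = 2) in M5, at least 4770-fold higher. PDZK1IP1, a small membrane protein (ENSG00000162366, chromosome 1, 47183593 to 47191044), went from 0 counts to 363 ± 4.51 CPM, at least 4070-fold higher. S100A9, a subunit of calprotectin (ENSG00000163220, chromosome 1, 153357854 to 153361027), rose from 1.75 ± 0.365 to 2960 ± 315 CPM, a log2 fold change of 10.72 (SE 0.12, edgeR adjusted p = 6.65e-22). SERPINB4, a serpin of squamous epithelia (ENSG00000206073, chromosome 18, 63637259 to 63644298), rose from 0.95 ± 0.413 to 1630 ± 141 CPM, a log2 fold change of 10.73 (SE 0.13). KRT13, a keratin of mucosal epithelia (ENSG00000171401, chromosome 17, 41500981 to 41505705), fell from 209 ± 13.2 to 2.20 ± 0.200 CPM, 94.6-fold lower (SE of the log2 value 0.11, edgeR adjusted p = 8.70e-20).

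The other genes among the 8 largest rises also had 0 counts in both PBS libraries, so their ranks depend on the prior count of the fit. Their bounds lie below the 1420-fold rise of CSF3, which is not among the 8. S100A7A was at least 519-fold higher, PPBP, a platelet chemokine next to CXCL5 on chromosome 4, at least 425-fold, TNIP3, an inhibitor of NF-kB signalling, at least 374-fold, and BCL2A1, an anti-apoptotic BCL2 relative, at least 245-fold. Among the falls, ALPG, a germ cell alkaline phosphatase (chromosome 2, 232406843 to 232410714), went from 10.1 ± 1.38 CPM to 0 counts in both M5 libraries, at least 124-fold lower. Its neighbour ALPP, the placental alkaline phosphatase (chromosome 2, 232378534 to 232382889), fell from 91.6 ± 0.165 to 0.735 ± 0.0617 CPM, 124-fold lower. KRT4, the partner keratin of KRT13, fell from 55.0 ± 1.60 to 0.192 ± 0.121 CPM, 278-fold lower, with a log2 value of -8.12 that became -8.91 without M5 replicate 1. CPA4, a carboxypeptidase, fell 48.9-fold and SOST, which encodes the WNT inhibitor sclerostin, 46.5-fold. KRT3 fell by 4.46 on the log2 scale, with values of -5.60 and -3.80 without M5 replicate 1 and 2. CCNB1IP1 (chromosome 14, 20311368 to 20333312) rested on 1 library: its counts were 10 and 272 in PBS and 4 and 8 in M5, and its log2 fold change of -4.65 (edgeR adjusted p = 0.000373) became -0.86 without PBS replicate 2 and -5.59 without PBS replicate 1, with adjusted p over its alternatives from 6.16e-56 to 0.453.

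**Figure D1:**
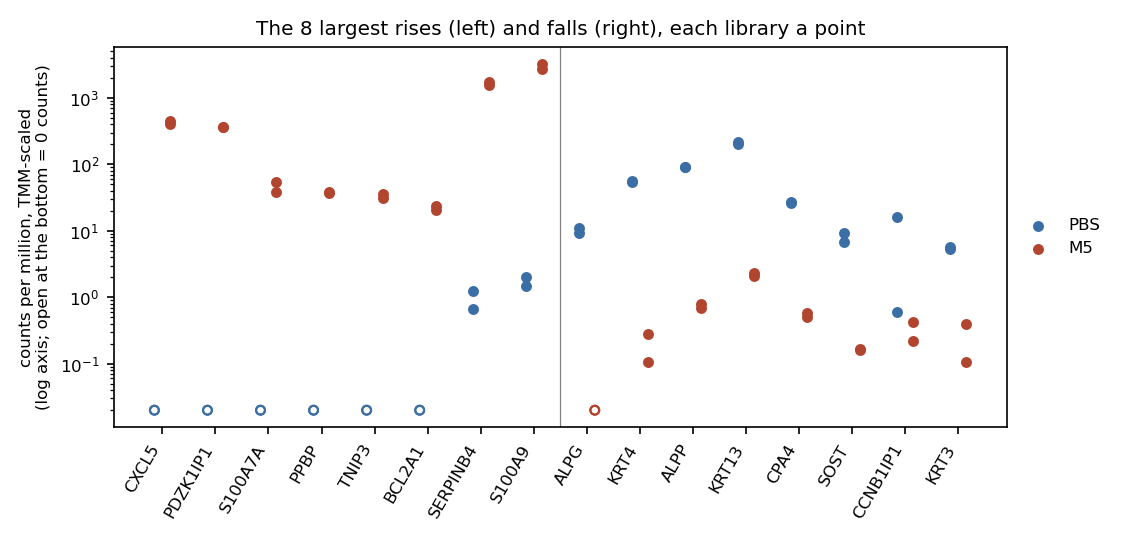
TMM-scaled CPM (log axis) of the 8 genes with the largest rise and the 8 with the largest fall, 1 point per library, PBS in blue and M5 in red, with open points at the bottom for 0 counts. S100A9 went from a mean of 1.75 to 2960, and the PBS libraries of CCNB1IP1 lie apart.

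Of 10809 genes tested, 6043 (55.9%) changed, 3114 higher and 2929 lower in M5, and 1039 of them changed at least 2-fold, 700 higher and 339 lower. The genes that rose at least 2-fold held 3.8% of the PBS counts and 12.2% of the M5 counts. The balance of directions depended on the scaling. With library totals in place of TMM, 2201 genes were higher and 4463 lower, and with TPM scaling 2027 were higher and 4739 lower. The planned limma test on log2(FPKM + 1), which applies no TMM factors, called 2010 higher and 4122 lower. The median log2 fold change of all tested genes, -0.01 with TMM, was -0.16 with totals and -0.19 with TPM, so changes below are relative to the TMM median. At 2-fold, 67.4% of the changed genes were higher with TMM, 53.2% with totals and 50.2% with TPM.

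Genes of cytokine signalling rose together. Among antimicrobial peptides and S100 alarmins, all 9 tested members rose, with a median log2 fold change of 9.11, or 9.02 with genes at 0 counts set at their bound and 10.45 without PBS replicate 2 (camera adjusted p = 3.75e-87, adjusted p = 0.085 with an estimated correlation). S100A8, the calprotectin partner of S100A9, rose by a log2 value of 10.37 (11.01 without PBS replicate 2). All 9 tested chemokines rose, with a median of 5.90, or 5.77 with bounds and 5.30 without a filter, where 13 of 17 rose (camera adjusted p = 9.11e-47, adjusted p = 0.085 with an estimated correlation). CCL20, which draws CCR6-bearing lymphocytes, had 0 counts in PBS and was at least 54.0-fold higher, and CXCL3 rose by 7.83 (8.57 without PBS replicate 1). Of 15 interleukin and colony-stimulating factor genes, 13 rose and 1 fell, with a median of 4.38 (camera adjusted p = 3.59e-20, adjusted p = 0.089 with an estimated correlation). CSF3, the granulocyte growth factor, rose by 10.47 (SE 0.15). IL24 was 464-fold higher (exact 95% interval 128 to 3840) and IL36G, an epithelial cytokine of the interleukin 1 family, 299-fold (102 to 1450), both against 1 to 3 counts in PBS, and the log2 value of IL24, 8.70, was 11.95 and 7.77 without PBS replicate 1 and 2. The value 11.95 is against a PBS library with 0 counts and depends on the prior count of the fit.

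Of 17 NF-kB feedback and target genes, 16 rose, with a median of 1.75 (camera adjusted p = 5.46e-31, adjusted p = 0.085 with an estimated correlation), including ICAM1, a leukocyte adhesion receptor, by 5.08, SOD2, the mitochondrial superoxide dismutase, by 4.09, and TNFAIP3, an inhibitor of NF-kB signalling, by 3.81. All 15 tested STAT3 pathway and target genes rose, with a median of 1.30 (camera adjusted p = 6.29e-18, adjusted p = 0.085 with an estimated correlation). The suppressors of cytokine signalling SOCS3 and SOCS1 rose by 4.53 and 3.80, and LRG1 by 3.30. All 7 tested receptors of the M5 cytokines rose, with a median of 1.18 (camera adjusted p = 1.51e-06, adjusted p = 0.089 with an estimated correlation), led by the decoy receptor IL1R2 at 2.53, OSMR at 1.97 and IL1R1 at 1.21. With library totals or TPM scaling 5 of them rose. Without a filter all 12 receptor genes were tested, the median was 0.22, 7 rose and 2 fell: IL22RA1, a chain of the interleukin 22 receptor, at -0.97, and TNFRSF1B, the second TNF receptor, at -1.63, both chosen after their values were seen. Of 17 interferon-stimulated genes 16 rose, with a median of 1.51 (camera adjusted p = 8.63e-14, adjusted p = 0.19 with an estimated correlation), among them IFI6 by 5.01, RSAD2 by 3.87 and OAS2 by 2.63. All 4 tested complement and acute phase genes, too few for camera, rose. The filter takes the mean over all libraries, so genes near 0 in PBS were tested only where M5 was high. Without a filter 9 of 15 complement and acute phase genes rose and 0 fell. C1S, a complement protease, rose by 5.97, SAA2 by 7.64 (8.87 without PBS replicate 2, and a fold 1.56 times lower without PBS replicate 1) and SAA1 by 4.41 (5.32 without PBS replicate 2). Of 6 tested antigen presentation genes 5 rose, with a median of 0.82 (camera adjusted p = 0.00746, adjusted p = 0.29 with an estimated correlation). These were led by PSME1, a proteasome activator subunit, at 2.87 (2.28 without M5 replicate 2), HLA-B at 1.44 and its partner chain B2M at 1.04. PSME1, HLA-B and B2M each have a transcript outside the primary genome assembly, and 48.3% of autosomal protein-coding genes of that kind had a row in the tables used here, against 80.4% of the others. Without genes of that kind fewer than 5 members remained, so the list could not be tested.

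Of the cytokines added, IL1A was also expressed by the cells and rose from 22.5 ± 0.974 to 692 ± 62.6 CPM, a log2 fold change of 4.94 (SE 0.08, edgeR adjusted p = 9.15e-20). OSM had 1 count in 1 PBS library and 0 counts in the other 3 libraries. IL17A, IL22 and TNF have no row in the tables used here. No gene with a row had 0 counts in all libraries, so a missing row may mean that no read was counted.

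Keratinocyte genes moved in both directions. Of 10 tested psoriasis lesion genes 9 rose, with a median of 3.83 (camera adjusted p = 3.50e-33, adjusted p = 0.089 with an estimated correlation), led by SERPINB4, SERPINB3 (log2 value 8.44, SE 0.12) and IL36G. Without a filter the median was 2.80, and 14 rose and 1 fell. All 4 tested stress keratins, too few for camera, rose. KRT6B rose by 6.39 (7.25 without PBS replicate 1), KRT16 by 3.16 and KRT17 by 2.17. All 7 tested SPRR and LCE3 genes, cornified envelope precursors, rose, with a median of 5.00, also with bounds (camera adjusted p = 0.00091, adjusted p = 0.19 with an estimated correlation). Without a filter 9 of 12 rose and 0 fell. SPRR2A had 0 counts in PBS and was at least 127-fold higher, while SPRR2D was 145-fold higher (exact 95% interval 25.7 to 5780) and LCE3D 93.3-fold (31.6 to 455), against 1 to 3 counts. The log2 value of SPRR2D, 6.87, was 6.03 and 9.27 without PBS replicate 1 and 2, and that of LCE3D, 6.43, was 10.22 and 5.48. The values 9.27 and 10.22 are against a PBS library with 0 counts and depend on the prior count of the fit. Of 15 basal keratinocyte and basement membrane genes 11 rose and 3 fell, with a median of 0.80 (camera adjusted p = 2.73e-08, adjusted p = 0.16 with an estimated correlation). Those that rose included the laminin chain LAMA3 at 1.72 and the integrin ITGA2 at 1.67. The 3 that fell, named after their values were seen, were the keratins KRT15 and KRT5 and the collagen COL7A1. Their log2 values without a filter were -1.45, -0.94 and -0.45, and the keratin KRT14 was at 0.30.

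Other differentiation genes moved in both directions, and in the cornified envelope and barrier list more fell than rose. Of 10 tested cornified envelope and barrier genes 6 fell and 3 rose, with a median of -0.68 (camera adjusted p = 7.67e-06, adjusted p = 0.089 with an estimated correlation). Filaggrin (FLG) fell 11.0-fold and the desquamation proteases KLK5 and KLK7 fell 8.60-fold and 6.11-fold. Of 7 simple and mucosal keratins 4 fell and 2 rose, with a median of -0.14 (camera adjusted p = 1.51e-06, adjusted p = 0.094 with an estimated correlation); next to KRT4 and KRT13, KRT80 fell 4.33-fold. The calls for both lists were lost with limma on log2(FPKM + 1), with medians of -0.77 (camera adjusted p = 0.109) and -0.29 (camera adjusted p = 0.223). The median of all tested genes was -0.14 in that fit, so these medians cannot be set directly against those with TMM. The call for the keratins was also lost without a filter (median -0.11). Of 7 tested spinous differentiation genes, 2 rose and 3 fell, with a median of -0.16 (camera adjusted p = 0.797). Without a filter 4 of 16 rose and 5 fell. Among the latter was KRT1, chosen after its values were seen, with 44 and 76 counts in PBS and 0 in both M5 libraries (edgeR adjusted p = 2.83e-05). OVOL1 fell by 0.61, and NOTCH3 had a log2 value of -0.50 (edgeR adjusted p = 0.00857) that did not pass without PBS replicate 1 (-0.39) or with quantile normalization (-0.27).

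Genes of matrix turnover and growth factor signalling rose. Of 16 matrix protease and plasminogen genes 12 rose and 2 fell, with a median of 2.42 (camera adjusted p = 4.71e-28, adjusted p = 0.085 with an estimated correlation). The metalloproteases MMP10, MMP1 and MMP3 rose by 6.54, 5.46 and 5.11 (MMP3 5.70 without PBS replicate 1). Of 12 EGF receptor ligand and feedback genes 10 rose and 1 fell, with a median of 1.29 (camera adjusted p = 3.53e-13, adjusted p = 0.085 with an estimated correlation), including the ligands HBEGF at 4.21 and AREG at 2.75 and the phosphatase DUSP5 at 2.12. Of 15 glycolysis and hypoxia genes 13 rose, with a median of 0.39 (camera adjusted p = 2.59e-07, adjusted p = 0.089 with an estimated correlation), led by NDRG1 at 2.04, BNIP3 at 2.04 and ADM at 2.02, and 9 rose with library totals or TPM scaling. The glycolysis genes LDHA and ALDOA, chosen after their values were seen, did not pass the filter. Each library held at most 56 counts of either, against at least 70617 of PKM, and the reason was not tested. Of 14 p53 target genes 9 rose and 1 fell, with a median of 0.38 (camera adjusted p = 0.00353, adjusted p = 0.21 with an estimated correlation). The cell cycle inhibitor CDKN1A rose by 3.23, the pro-apoptotic BBC3 by 1.73 and TP53I3 by 1.19. Of 14 adhesion and tight junction genes 8 rose and 3 fell, with a median of 0.16 (camera adjusted p = 0.0119, adjusted p = 0.18 with an estimated correlation), including CDH3 at 1.72, DSC2 at 1.15 and CLDN1 at 1.07. Of 9 mesenchymal transition genes 4 rose and 3 fell, with a median of 0.13 (camera adjusted p = 0.0154, adjusted p = 0.19 with an estimated correlation): the integrin ITGA5 rose by 3.51, while SPARC fell 5.53-fold and TGFB2 3.73-fold. With TPM scaling 5 adhesion genes rose and 6 fell, the median was -0.02 and the call was lost, as it was with a mean FPKM of at least 5, and with totals 5 rose and 4 fell. The mesenchymal median was -0.05 with TPM scaling, -0.02 with totals and 0.75 with a mean FPKM of at least 5. Both the adhesion and the mesenchymal call were lost with limma on FPKM, and the mesenchymal call also without a filter and without PBS replicate 1 or 2.

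Cell cycle genes fell. All 20 tested G2/M genes fell, with a median of -0.59 (camera adjusted p = 1.96e-08, adjusted p = 0.089 with an estimated correlation), led by the mitotic proteins CENPF, 1.87-fold lower, KIF20A, 1.79-fold, and KIF11, 1.75-fold. Of 20 G1/S genes 15 fell and 1 rose, with a median of -0.55 (camera adjusted p = 4.41e-06, adjusted p = 0.089 with an estimated correlation). TYMS, which makes thymidylate, fell 2.09-fold and GINS2, a replication factor, 1.84-fold, whereas the cyclin gene CCNE1 rose by 0.93 (SE 0.12, edgeR adjusted p = 3.01e-06).

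Besides the spinous genes, camera did not call 5 tested lists at its main settings. It called the mitochondrially encoded genes down with quantile normalization in limma (median -0.42) and the unfolded protein genes up without a filter (median 0.16). Fry, which does not compare a list with other genes, called the cholesterol (adjusted p = 0.0357), unfolded protein (adjusted p = 0.0233) and immediate early lists (adjusted p = 0.0415). The medians of these 3 lists, 0.04, 0.13 and 0.10, were -0.14, -0.05 and -0.08 with TPM scaling. The counts given next are with TMM, and with TPM scaling 3 rose and 9 fell in the cholesterol list, 7 and 9 in the oxidative stress list, 5 and 3 in the unfolded protein list, 3 and 3 in the immediate early list and 1 and 10 in the mitochondrial list. Of 17 cholesterol synthesis genes 6 rose and 5 fell (camera adjusted p = 0.962), among them MSMO1, higher by 0.73, and ACAT2, 1.68-fold lower. Of 19 oxidative stress genes 7 rose and 6 fell (camera adjusted p = 0.919), with the metallothionein MT2A higher by 2.41, heme oxygenase HMOX1 by 2.12 and GCLC 2.35-fold lower. That list had a median of 0.30 but a camera direction of down. Of 14 unfolded protein and amino acid stress genes 7 rose and 2 fell (camera adjusted p = 0.797), with DNAJB9 higher by 1.30, CHAC1 by 1.22 and PHGDH 2.27-fold lower. Of 7 immediate early and heat shock genes 3 rose and 1 fell (camera adjusted p = 0.671), with FOS higher by 1.19, IER2 by 0.92 and JUN by 0.53. Of the 13 mitochondrially encoded genes 2 rose and 6 fell (camera adjusted p = 0.559). MT-ND6 was higher by 0.56, which did not pass with quantile normalization, MT-ND2 fell by 0.36 and MT-CO3 by 0.20, the last not past the threshold without PBS replicate 1 (-0.18), without a filter or with quantile normalization.

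Few markers of other cell types passed the filter. Of the fibroblast list 1 gene was tested and fell, FBLN1, from 48.2 ± 5.84 to 29.9 ± 0.639 CPM, and of the melanocyte list 1 gene was tested and fell, MITF, from 13.3 ± 0.0190 to 7.19 ± 0.535 CPM. Both tested genes of the leukocyte list rose, CD14 from 3.01 ± 0.822 to 8.45 ± 0.540 CPM. No endothelial marker passed the filter, and CDH5 had 1.04 ± 0.202 CPM in PBS and 3.30 ± 0.896 in M5, a rise when no filter was used (log2 value 1.69, edgeR adjusted p = 0.0031), where VWF, chosen after its values were seen, fell from 19 and 11 counts to 3 and 0 (log2 value -3.31, edgeR adjusted p = 0.0223). Of 26 germline genes silenced by DNA methylation, 4 had a row and 1 was tested: HORMAD1, at 3.21 ± 0.361 CPM in PBS and 3.86 ± 0.263 in M5, did not pass (edgeR adjusted p = 0.385).

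**Figure D2:**
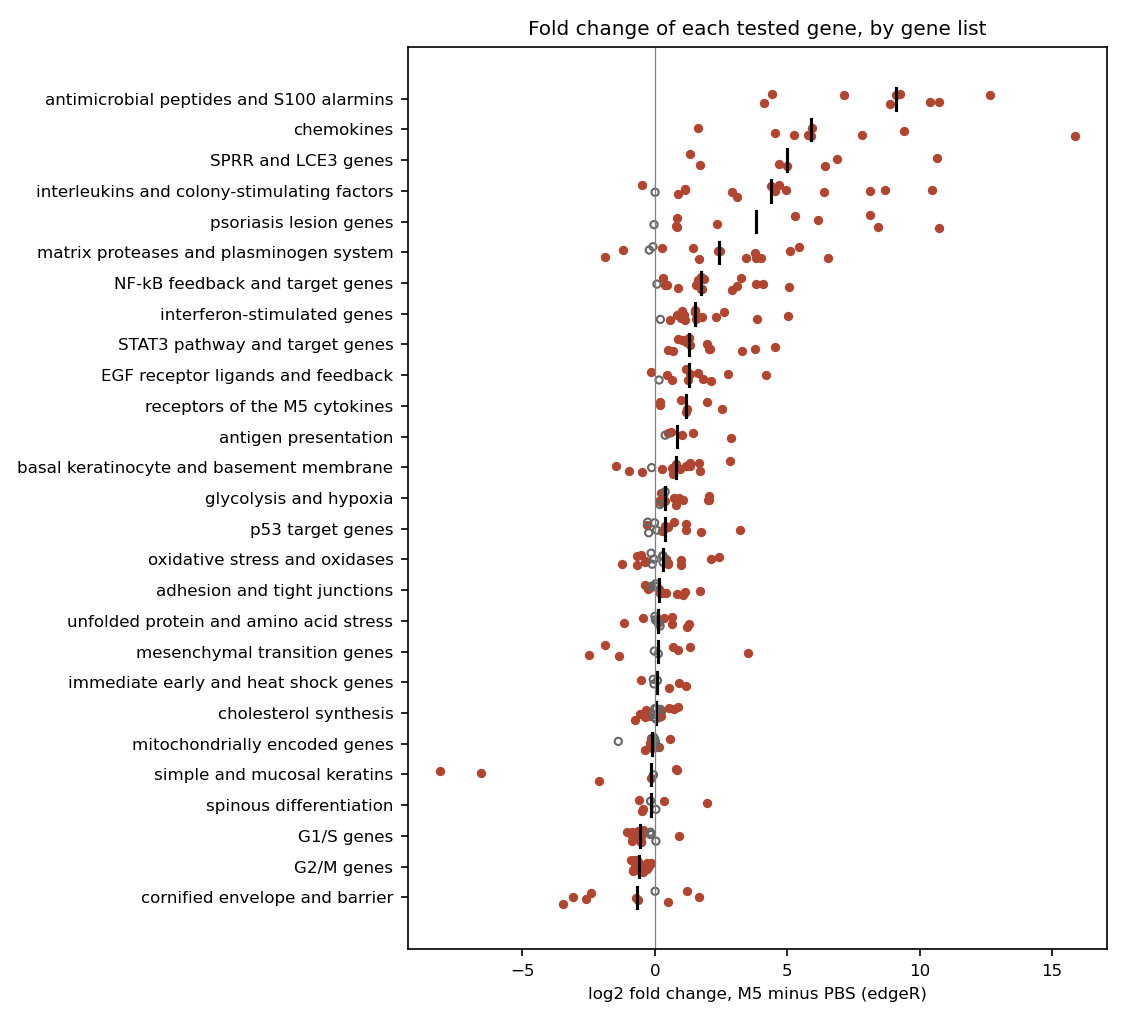
Log2 fold change (M5 minus PBS, edgeR) of each tested gene, by gene list with at least 5 tested members, filled where the adjusted p was under 0.05, with a black bar at the list's median. Medians run from -0.68 for cornified envelope genes to 9.11 for antimicrobial genes, and values of genes with 0 counts in a group depend on the prior count.

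Camera called 21 of the 27 lists tested, 17 up and 4 down. No call held with an estimated correlation, where the model has 2 residual degrees of freedom, the smallest adjusted p was 0.085 and 14 lists had an unadjusted p under 0.05, while fry called 24. With limma on log2(FPKM + 1) the medians were 6.65 for antimicrobial genes, 3.71 for chemokines, 1.95 for interleukins, 2.30 for psoriasis genes and 2.41 for SPRR and LCE3 genes. Adjusted over the list alone, the counts of changed members were those over all genes except for 16 falls in the G1/S list and 4 in the adhesion list. How reads of near-identical genes were counted is not given, so the split between ALPP and ALPG, SERPINB3 and SERPINB4, SAA1 and SAA2, S100A7A and its relative S100A7, KRT6B and other KRT6 genes, and among SPRR2 genes is uncertain.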

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

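Added as alternatives only after the data were seen were limma on log2(FPKM + 1), which had been the planned test, DESeq2, library totals, the robust edgeR fit and the tests without discordant genes or without genes that have a transcript outside the primary assembly. The number of changed genes, 6043, stayed within 1.5 times under every alternative, from 4204 with a mean FPKM of at least 5 to 6766 with TPM scaling, and were 5150 with DESeq2, 4853 at an adjusted p of 0.01 and 4974 to 6006 with 1 library left out. The genes called were not all the same: of the 6043 calls, 1162 were lost with limma on log2(FPKM + 1), 1087 with TPM scaling, 1182 without PBS replicate 1 and 2078 with a mean FPKM of at least 5, where part of them were not tested. With 1 library left out, the lone library is assumed to vary like the other group. Whether same-numbered libraries were paired is not stated. Their deviations had a correlation of -0.013 across genes, which does not exclude a pairing that affects few genes, and the replicate block called 6091. The 1039 genes changed at least 2-fold became 647 with limma on log2(FPKM + 1), 658 with quantile normalization, 645 without trend, 644 with limma's robust fit, 497 with a mean FPKM of at least 5, where fewer genes are tested, and 1867 without a filter, where more are. The pseudocount lowers folds of low genes in limma, where 0.1 gave 1009, with 546 higher and 463 lower against 700 and 339 in the main fit. The directions of all changed genes moved more than their number, from 3114 higher and 2929 lower to 2010 and 4122 with limma on log2(FPKM + 1). Of the 21 lists called, 0 passed with an estimated correlation, and 17 were lost in no other alternative in which they were tested (highest other adjusted p 0.028). The antigen presentation list was tested in 19 settings and the SPRR and LCE3 list in 20, against 21 for the other lists called. Lists were not tested with DESeq2. For 3 lists not called, the direction of camera or fry reversed: cholesterol synthesis, with medians of 0.04 (fry), 0.04 (no filter) and -0.01 to 0.05 with 1 library left out, and oxidative stress, with 0.30 (fry), 0.08 (limma), 0.12 and 0.10 (pseudocounts of 0.1 and 0.5), 0.17 (quantile), 0.08 (no trend), 0.08 (limma robust), 0.33 (no filter) and -0.05 to 0.33 with 1 library left out. The third was the immediate early genes, with a median of -0.20 under quantile normalization, where MT-CO3 had a log2 value of 0.00; the cause was not tested for any reversal. Of the comparisons of a named gene with an alternative, 1972 kept direction and call, 13 lost the call (CCNB1IP1, NOTCH3, MT-ND6 and MT-CO3) and 1 reversed (MT-CO3). Most named genes were picked for large changes in the main fit, so these comparisons do not measure how stable the calls are in general. Depth limits genes near the floor, where a few counts in PBS set the fold.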

Other observations

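All tests in this part except that of the treatment tag were chosen after the result was seen. Beside the lists fixed beforehand, 28 families of protein-coding genes were compared with the other genes, and those that share members with the lists were compared again without these members. All 8 tested kallikrein-related peptidases, serine proteases of which several act in desquamation, fell, with a median log2 fold change of -2.71 (camera adjusted p = 2.90e-09, adjusted p = 0.28 with an estimated correlation), from KLK6 at -3.83 to KLK8 at -1.15. The 6 of them outside the lists had a median of -2.50 (camera adjusted p = 0.000629, adjusted p = 0.86 with an estimated correlation). Of 15 interleukin receptor genes 11 rose and 3 fell (camera adjusted p = 5.09e-05, adjusted p = 0.28 with an estimated correlation), and of the 10 outside the lists 6 rose and 3 fell (camera adjusted p = 0.0128, adjusted p = 0.86 with an estimated correlation). IL13RA2, a decoy receptor of interleukin 13, rose by 5.97 and IL7R by 2.72, while IL17RE and IL20RA fell by 1.63 and 1.44.

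Of 72 cytosolic ribosomal protein genes 44 fell and 1 rose, by a small median of -0.19 (camera adjusted p = 0.00322, adjusted p = 0.73 with an estimated correlation), and of 66 mitochondrial ribosomal protein genes 35 fell and 2 rose (camera adjusted p = 0.0146, adjusted p = 0.61 with an estimated correlation). Of 10 aldehyde dehydrogenases 5 fell and 2 rose (camera adjusted p = 0.0146, adjusted p = 0.35 with an estimated correlation), with ALDH3A1 at -3.54 and ALDH3B1 at -3.05. Camera also called clade B serpins, S100 proteins and integrins, but not without the list members (camera adjusted p = 0.103, 0.101 and 0.804), where 3 integrins rose and 4 fell. It called laminins and mini-chromosome maintenance genes too, of which 4 and 3 lie outside the lists, too few to test, and did not call the other 18 families. The medians of the families named here, with all members, kept their sign with median-of-ratios, TPM and total scaling. TPM and total scaling move all genes down (overall medians of -0.19 and -0.16), so under them only families with a median above 0 could have changed sign.

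The treatment tag of the M5 libraries names DAC, where the titles name M5. Were the cells given a DNA-demethylating drug and not the cytokines, the prediction written beforehand was that at least 5 listed germline genes appear and fewer than 3 antimicrobial genes rise. In these libraries 9 antimicrobial genes rose, which argues against a drug in place of the cytokines if such a drug does not raise these genes. That condition was assumed and not tested. The germline genes are not counted as evidence, since 22 of the 26 have no row. No gene with a row had 0 counts in all libraries, so a missing row may mean that no read was counted. Rows were also missing more often for genes with a transcript outside the primary assembly, so reads may have been lost instead. A drug given in addition was not tested.

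In 44 genes, with at least 100 counts in a group, the CPM differed at least 3-fold between the replicates of a group, where binomial sampling of the counts would give 8.8e-05 such genes. LY6E, chosen after its values were seen, had 106 and 1381 counts in PBS and 53 and 51 in M5. Of the 43 that code for protein, 62.8% have a transcript outside the primary assembly (patches and alternate loci) in GENCODE 29, against 1.2% of 10393 other genes with as many counts (Fisher's exact p = 1.9e-40). Among 10449 genes with at least 100 counts in both groups, 15 were discordant in PBS and 11 in M5, and 8 were discordant in both where 0.02 are expected by chance. A candidate explanation is that reads shared with another copy of the locus were counted in some libraries and lost in others. It leaves open the genes without such a transcript, CCNB1IP1 among them, and no biological explanation was tested.

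The S phase and mitosis genes had medians below 0 under each of TMM, median-of-ratios, TPM and total scaling. The medians nearest to 0 were -0.54 for the G1/S list and -0.58 for the G2/M list. TPM and total scaling move all genes down (overall medians of -0.19 and -0.16), so they could not bring the lists nearer to 0. The test therefore does not decide on scaling as the cause, though both lists lay below the median of all tested genes under each scaling. A lower share of dividing cells after M5 may account for the fall, and so may a difference in cell density at harvest. Neither was tested, since the labels give the density only at the start of treatment.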
